A study of Mus musculus with 9 samples.

How the data were processed

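The series holds 9 polyadenylated RNA libraries of mouse J1 ES cells in 8 groups, described in 1 table of gene-level values. The authors deposited FPKM values (fragments scaled by transcript length and by the mapped fragments of a library), and per the submitters' processing notes the tools were TopHat2 and Cuffdiff and the genome build was mm9. Versions, the gene annotation, strandedness and read length are not given in the sources used here. The file itself does not write the unit beside its columns; the values were taken as FPKM because Cuffdiff gives that unit and the steps between low values depend on the gene. Cuffdiff scales libraries against each other, and it estimates values by likelihood, so a 0 can be a failed estimate. Serbp1 is listed at 0 in 4 libraries and at 220 FPKM or more in the others, and such genes are given only as listed at 0. Genes with many near-identical copies, such as Gapdh, stood at very low values and are uncertain.

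The table has 23277 rows, of which 4746 are blank. Another 27 rows carry a symbol that a spreadsheet had turned into a date and were left out, which left 18504 genes. Small RNA rows (177, by RefSeq biotype or symbol) took 16.0% to 23.8% of the summed FPKM per library although the RNA was polyadenylated and these transcripts are shorter than a usual fragment. Their values are large and jump to 0, and the 2-fold counts between libraries and the main limma counts are therefore also given without them. Columns were matched to samples by title, and no column was left unmatched. The reference in hand is GRCm38, another build than mm9, and it was used for transcript lengths, GC content, symbols and biotypes only, so no coordinates are given.

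Depth was recovered from the FPKM steps. Each library was set against BirA over genes under 1 FPKM but above 0 in both. Of these genes 8.08% to 11.4% shared 1 most common ratio, which was read as the ratio of 1 fragment's value and so of depth. The scale came from 235 genes under 2 FPKM in every library with 1 annotated transcript of at least 3000 nt, by transcript length. It had quartiles of 12.6 to 14.8 M (mega) fragments for BirA. The estimates, in M fragments, were 14.6 for BirA, 21.9 for the overexpression library, 14.8 for ESC, 9.20 and 12.6 for the libraries labelled Yap1_KO1 and Yap1_KO2, 22.3 for the knockdown control, 18.0 for the knockdown, 19.2 for the differentiated control and 13.1 for the differentiated knockdown. They are effective depths, since Cuffdiff's scaling may be part of them. Whole counts were not used in a test.

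All tests, log2 ratios and 2-fold counts were computed on log2(FPKM + 1), over genes at 1 FPKM or more in at least 1 library compared, so log2 ratios of low genes are understated. Correlations used genes at a mean of 5 FPKM or more. Percentages of a control and fold differences of single named genes are ratios of FPKM. Comparisons of 1 library with 1 count genes at least 2-fold apart and give no p-value. The knockout-labelled libraries against ESC (1 residual degree of freedom) and the joint fit of both arms with an arm term (2 residual degrees of freedom) used limma 3.58.1 in R 4.3.3 with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. The lone controls are assumed to vary like the knockout pair. Nothing in the labels says that the pair came from separate clones or cultures, so p-values measure only the spread between these samples, which may be technical. On simulated data with 200 changed genes of 11538, the knockout fit recovered 11% of 2-fold and 83% of 4-fold changes, and 24.2% of its calls were false. The joint fit, on 12128 genes, recovered 82% and 95%, with 0.562% false. The simulation took all noise from the knockout pair, gave both arms the same change, held no GC trend and changed only genes at 5 FPKM or more. In it limma gave 3.75% and 3.66% of unchanged genes an unadjusted p under 0.05. In the data 23.1% and 6.75% of all genes had one, so these rates do not carry over to the real fits.

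Groups, tests, the 27 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A list's median log2 ratio was placed among medians of 10000 random lists of the same size matched on mean expression in 20 bins. Named genes are the 10 highest and 10 lowest log2 ratios among genes at 5 FPKM or more in a compared library (for the knockout and joint comparisons ranked by the smallest ratio over the perturbed libraries), Yap1 and Wwtr1, and up to 4 members of each list. In single-library comparisons 9 or 10 of each 10 were small RNAs. The same ranking without small RNAs and without abundant genes listed at 0 was therefore added after the data were seen, and most named genes come from it or from the lists. Other genes were chosen after their values were seen. These are Pou5f1, Nanog and Sox2 where named as close to a control or lower in differentiation, Ajuba, Mt1, Mt2 and Trh in the knockout comparison, Trh in the knockdown in ES cells, Ctgf and Klf4 in differentiated cells, the list members named as passing, and the genes of the closing section.

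Other settings tried were a pseudocount of 0.1 or 5 FPKM, no filter or one at 5 FPKM, median-of-ratios rescaling, limma without trend or with a robust prior, all 3 undifferentiated controls, 1 control library per knockout-labelled library, no arm term, and leaving out each knockout-labelled library. Added after the data were seen were the removal of small RNA rows, ESC or the mean of the 3 undifferentiated controls in place of a comparison's own control, and the removal of a GC trend. For the last, a lowess curve (span 0.3) of each library's deviation from the mean of all libraries on GC content of the longest transcript was subtracted; 95.6% of genes at a mean of 1 FPKM or more had a GC value, and the rest took the correction at the median. Unchanged samples against 1 shared control were simulated 100 times from the differences of the knockout pair. Figures and summaries were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.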

Results

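Polyadenylated RNA was sequenced from 9 libraries of J1 cells, a mouse embryonic stem (ES) cell line of the strain 129S4/SvJae, at passage 5 to 7. Yap1 is the transcriptional coactivator that the Hippo kinase pathway holds in the cytoplasm, and it acts on DNA through the TEAD proteins. The libraries form 8 groups. They are an overexpression library (Yap1_OE) with its control BirA, 2 libraries labelled as knockouts (Yap1_KO1 and Yap1_KO2) with the control ESC, a knockdown library (Yap1_KD) with its control, and a differentiated pair in which ES cells had been differentiated with or without the knockdown. Every group except the knockout group has 1 library, so differences between single libraries have no replicate check and carry no p-value. The estimated depth ran from 9.20 M (mega) fragments in Yap1_KO1 to 22.3 M in the knockdown control. A level of 1 FPKM of a 2 kb transcript stood for about 18.4 fragments in Yap1_KO1 and 44.7 in the knockdown control.

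Yap1 RNA was examined first in every library. In the overexpression library Yap1 stood at 139 FPKM against 46.7 in BirA, a 2.98-fold higher level. In the knockdown library Yap1 stood at 4.55 FPKM against 37.4 in the control, which is 12.2% of the control. In differentiated cells it stood at 12.5 FPKM under knockdown against 78.0 in the control, or 16.0%. The libraries labelled as knockouts kept Yap1 RNA. The library labelled Yap1_KO1 had 57.3 FPKM and the library labelled Yap1_KO2 27.6 FPKM, against 65.4 in the ESC control, or 87.6% and 42.2%. The log2 ratio of the pair was -0.70 with a standard error of 0.45 (limma, Benjamini-Hochberg adjusted p = 0.402). What was edited in these cells is not given in the sources used here, and a gene-level FPKM cannot show a small deletion. Directions below that rest on these libraries are directions of the libraries labelled Yap1_KO1 and Yap1_KO2. Wwtr1, the paralog of Yap1 also called TAZ, lay between 7.55 and 10.2 FPKM in the 7 undifferentiated libraries. It was 27.2 FPKM in the differentiated control and 12.8 in the differentiated knockdown.

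**Figure D1:**
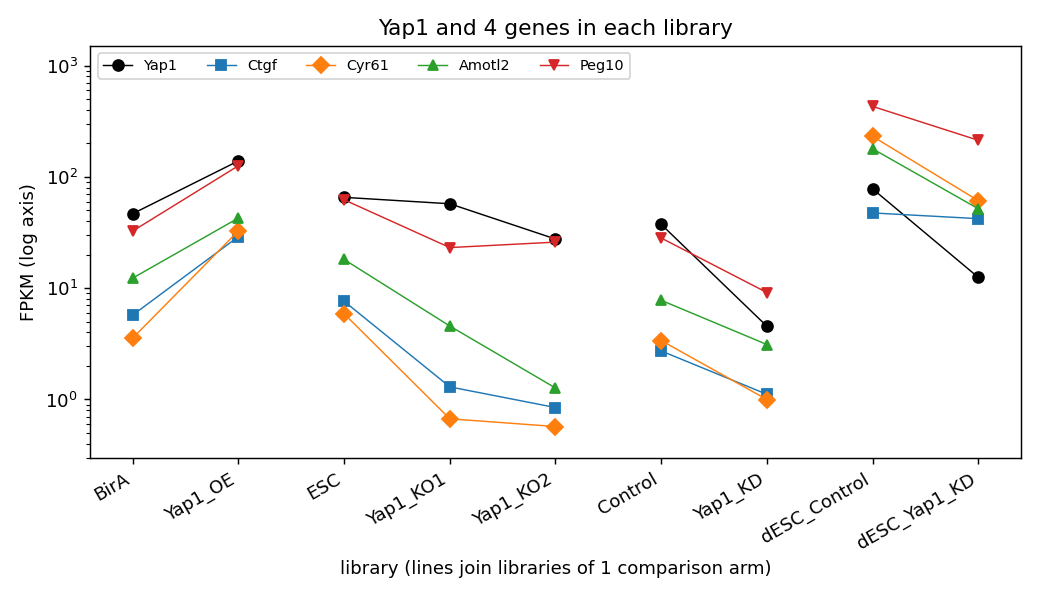
FPKM of Yap1, Ctgf, Cyr61, Amotl2 and Peg10 in each of the 9 libraries, on a log axis; each point is 1 library and lines join the libraries of an arm. Yap1 is at 139 FPKM in the overexpression library and at 4.55 in the knockdown. In the libraries labelled Yap1_KO1 and Yap1_KO2 it is at 57.3 and 27.6. Ctgf, Cyr61, Amotl2 and Peg10 are above their control in the overexpression library. These genes are below it in both knockout-labelled libraries and both knockdowns, Ctgf only slightly in differentiated cells (log2 ratio -0.17).

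The overexpression library addressed which genes differ when Yap1 RNA is raised in undifferentiated cells. Known YAP targets were higher than in BirA: Cyr61, a matricellular protein, was at 32.7 FPKM against 3.56, Ctgf, another of that family, at 29.0 against 5.74, and Amotl2, a YAP-binding junction protein, at 42.7 against 12.3. Of the 16 measured members of the YAP/TEAD target signature, 5 were at least 2-fold higher and 0 at least 2-fold lower. Of 10 trophoblast genes, 6 were at least 2-fold higher and 0 lower. The keratins Krt8 and Krt18, which form the first intermediate filaments of the early embryo, were at 63.4 and 130 FPKM against 7.32 and 17.5. The actin-binding protein Tagln was at 66.3 against 4.01, a 16.5-fold difference.

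Imprinted genes formed a second group in the overexpression library. The fetal growth factor Igf2 was at 29.2 FPKM against 1.49, the noncoding RNA H19, which shares its imprinting control region with Igf2, at 198 against 16.3, and Peg10, a retrotransposon-derived placental gene, at 126 against 32.6. In all, 7 of 18 imprinted genes were at least 2-fold higher and 0 at least 2-fold lower. The group of genes with lower values was led by hypoxia-response genes: the mitochondrial protein Ndufa4l2 was at 0.963 FPKM against 29.0, the mitophagy receptor Bnip3 at 4.97 against 30.2, and the glycolytic aldolase Aldoc at 4.92 against 29.5. All 19 glycolysis and hypoxia genes were below BirA, 6 of them at least 2-fold. The list also depends on the control: BirA over ESC had a median log2 ratio of 0.46 with 18 of 19 genes above 0, and the overexpression library over ESC had -0.38 with 3 of 19 above 0. The core factor Pou5f1 differed little, with a log2 ratio of -0.31. Tbx3, a transcription factor of naive ES cells, was at 16.4 FPKM against 44.8.

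Across 11599 genes, 186 were at least 2-fold higher in the overexpression library and 272 at least 2-fold lower. Without the small RNA rows the counts were 157 and 246. For scale, BirA against the ESC control, neither labelled for a change of Yap1, gave 131 higher and 79 lower, or 107 and 49 without small RNA rows. The knockdown control against ESC gave 357 and 225, or 308 and 200 without small RNA rows, so controls alone can differ by as many genes as the overexpression comparison. Among 24 fixed lists, 12 lay in the upper 2.5% of random lists of matched expression and 2 in the lower 2.5%. Lists of unrelated genes would give 1.2 in both tails together. Genes of a fixed list can move together between controls, as 18 of 19 glycolysis and hypoxia genes did in BirA over ESC. Lists were not placed for 1 control against another, so the excess over 1.2 cannot be assigned to Yap1. List medians on the log2 scale were 1.40 for trophoblast genes, 0.66 for imprinted genes, 0.63 for the YAP/TEAD target signature, 0.57 for p53 targets, 0.55 for formative and primed epiblast genes and 0.51 for actin cytoskeleton and SRF targets. Lower tails were reached by naive pluripotency (-0.40) and by glycolysis and hypoxia (-0.80). The other upper-tail lists were Hippo pathway components (0.36), neuroectoderm (0.36), Nodal and BMP targets (0.33), endoderm (0.30), the integrated stress and unfolded protein response (0.24) and general pluripotency (0.16). With a filter at 5 FPKM neuroectoderm (percentile 64.4), Hippo pathway components (92.6) and endoderm (93.5) were no longer in a tail. Cell cycle (0.017), pro-apoptotic (0.018), mesoderm (0.031), immediate-early and heat shock (0.048), anti-apoptotic (0.19), Wnt target (-0.061), feeder fibroblast (-0.15), retinoic acid response (-0.35), histone (-0.025) and germline (-0.29) lists stayed within the random range.

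The libraries labelled Yap1_KO1 and Yap1_KO2 were compared with the ESC control. Canonical YAP targets were lower in both: Cyr61 had log2 ratios of -2.04 and -2.13 (5.88 FPKM in the control), Ctgf at 1.30 and 0.846 against 7.62, and Amotl2 at 4.57 and 1.27 against 18.1. Ajuba, a LIM protein that binds the Hippo kinase Lats, was at 18.7 and 14.8 against 70.0. Genes of other functions were lower as well, among them the keratin Krt17 (4.13 and 4.10 against 28.4), the transglutaminase Tgm1 (5.79 and 3.95 against 31.7), the secreted factor Fgf18 (0.382 and 0.558 against 5.71), the Nodal antagonist Lefty1 (13.4 and 11.6 against 39.1) and Dnmt3l, the cofactor of de novo DNA methylation (81.5 and 81.9 against 182). The uncharacterised gene D630045M09Rik was at 0.185 and 0.0676 FPKM against 17.3. On the higher side stood the ectonucleotidase Nt5e (5.09 and 5.66 against 0.714), the transferrin receptor Tfrc (65.1 and 66.2 against 26.4), transferrin itself, Trf (21.1 and 20.6 against 7.66), and the hormone precursor Trh (247 and 267 against 126).

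By limma with Benjamini-Hochberg adjustment over 11538 genes, 2 genes rose and 18 fell in the libraries labelled Yap1_KO1 and Yap1_KO2, and 17 of these 20 were small RNA rows. The other 3 were D630045M09Rik (log2 change -4.02, SE 0.20, adjusted p = 0.0213), Krt17 (-2.52, SE 0.13, adjusted p = 0.0213) and Snhg9 (-3.57, SE 0.21, adjusted p = 0.0346), the last listed at 0 in both knockout-labelled libraries. Without the small RNA rows, an alternative chosen after the data were seen, limma with Benjamini-Hochberg adjustment called 10 genes higher and 38 lower. These 48 included Ajuba (-2.01, SE 0.16, adjusted p = 0.0247), Cyr61 (-2.09, SE 0.22, adjusted p = 0.0320), Ctgf (-2.07, SE 0.23, adjusted p = 0.0358), Peg10, Dnmt3l, Tgm1, Lefty1 and the metallothioneins Mt1 and Mt2 among the lower genes. Tfrc, Trf, Nt5e, Trh and the Y-linked Ddx3y were among the higher ones. By limma an unadjusted p under 0.05 was reached by 23.1% of all genes. The log2 ratios followed the GC content of transcripts across genes in both libraries (Spearman rho -0.607 and -0.613). Between controls rho was -0.198 for BirA over ESC and -0.373 for the knockdown control over ESC. After the GC trend was removed 13.8% of genes had an unadjusted p under 0.05 by limma. Without small RNA rows 40 genes were then called, 35 of them among the 48. Of the genes named here, Ddx3y and Mt2 were not among the 40. With BirA and the knockdown control added as controls, 0 genes were called higher and 1 lower by limma, with 2660 genes at an unadjusted p under 0.05.

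Both knockout-labelled libraries were at least 2-fold from the ESC control in the same direction for 22 higher and 113 lower genes, and for 18 and 91 without small RNA rows. Unchanged samples simulated against 1 shared control gave on average 30.1 higher and 29.7 lower genes (at most 47 and 45), and 9.15 and 8.95 (at most 15 and 19) without small RNA rows. Independent lists of these sizes would share 0.442 higher and 3.26 lower genes. The log2 ratios of the pair correlated across genes at r = 0.645 against a simulated 0.498, with a covariance of 0.229 against 0.124. With the GC trend and small RNA rows removed the covariance was 0.0855 against 0.0320, and 17 genes were higher and 74 lower, where the simulation gave 8.81 (at most 18) and 8.40 (at most 17). With the GC trend removed the higher count thus lies within the simulated range. Without small RNA rows but with the trend kept, the 18 higher genes lie above the simulated maximum of 15. Part of the excess may still come from the shared control library, which cannot be split. The simulation drew the control's noise from the knockout pair as well, so larger differences between control libraries are not covered. By the 2-fold rule without small RNA rows, BirA against ESC gave 107 higher and 49 lower genes, and the knockdown control against ESC 308 and 200. Yap1_KO1 against ESC gave 51 and 165, and Yap1_KO2 against ESC 53 and 163.

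In the fit with small RNA rows, 0 of the fixed lists had members that passed over all genes by limma, while 2663 of all genes had an unadjusted p under 0.05. Without those rows the list members Cyr61, Ctgf, Nt5e, Peg10, Dnmt3l, Lefty1, Krt19, Sparc and Ddx3y passed over all genes. In the YAP/TEAD target signature 7 of 16 members passed by limma when Benjamini-Hochberg values were adjusted over the list alone: Amotl2, Ctgf, Cyr61, Igfbp3 and Nuak2 lower, Nt5e and Myof higher. With the GC trend removed 5 of them did. Its median was -0.096, within the random range. Imprinted genes had a median of -0.37, at percentile 0.03 of random lists, and Cdkn1c, an imprinted cell cycle inhibitor, and Peg10 passed when adjusted over the list alone. Wnt targets (-0.32), formative and primed epiblast genes (-0.25) and replication-dependent histones (-0.11) lay in the lower tail and germline genes (0.30) in the upper, and the histone and germline medians were 0.0085 and -0.073 with the GC trend removed. These 4 placements did not hold under other settings. Wnt targets were at percentile 4.05 with a pseudocount of 5 and 11.5 without a filter, and formative genes at 9.10 without a filter and 4.58 with the GC trend removed. Imprinted genes stayed in the tail under every setting run. In the glycolysis and hypoxia list 7 of 19 passed when adjusted over the list alone, 3 higher and 4 lower, and in the Nodal and BMP list 4 of 11. With the GC trend removed 4 (Egln3, Hk1, Pfkp and Pgam1) and 2 (Id1 and Lefty1) passed. The Y-linked genes Ddx3y, Eif2s3y and Uty were higher and passed when adjusted over the list alone, with 21.2 and 22.4 FPKM of Ddx3y against 7.12; after removal of the GC trend Ddx3y alone passed.

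The knockdown library asked the same of undifferentiated cells in which Yap1 RNA was at 12.2% of the control. Yap1 itself had the lowest log2 ratio among well-expressed genes that are not small RNAs, -2.79. D630045M09Rik was at 1.85 FPKM against 13.3, Peg10 at 9.14 against 28.2, Dnmt3l at 61.0 against 172, the growth factor receptor adaptor Grb10 at 10.8 against 31.0 and the protease Capn2 at 1.61 against 5.23. Among known targets Cyr61 was at 0.999 FPKM against 3.38, Ctgf at 1.11 against 2.73 and Amotl2 at 3.12 against 7.78. Higher values were found for Vax2, a homeobox factor of the ventral eye (7.15 against 1.84), for the glutamate receptor subunit Grin1 (10.8 against 3.25), for Dppa3, a naive and germline factor (9.96 against 3.91), and for Trh (170 against 76.4). Nanog (318 against 266), Pou5f1 (log2 ratio 0.15) and Sox2 (325 against 317) lay close to the control.

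Across 11861 genes, 60 were at least 2-fold higher and 60 lower under knockdown in ES cells, and 24 and 28 without small RNA rows. The 2 libraries labelled as knockouts differed from each other in 53 and 65 genes by the same rule. Without small RNA rows they differed in 30 and 38, which is more than the knockdown gave on those rows. These counts are not at like depth, with an estimated 9.20 and 12.6 M fragments for that pair. The knockdown control had 22.3 M and the knockdown 18.0 M. Of 24 lists, 5 lay in the upper and 5 in the lower tail. The lower ones were imprinted genes (median -0.31, with 2 of 16 at least 2-fold lower), formative and primed epiblast (-0.31), Wnt targets (-0.27), actin cytoskeleton and SRF targets (-0.26, with 2 of 14 above the control) and neuroectoderm (-0.26). The upper ones were interferon response (0.53), germline (0.51), the integrated stress and unfolded protein response (0.25), naive pluripotency (0.15) and replication-dependent histones (0.14). Without a filter neuroectoderm (percentile 10.3), Wnt targets (59.6), interferon response (92.2) and germline genes (95.3) left the tails. The YAP/TEAD target signature had a median of -0.12, with 2 of 15 members at least 2-fold lower, and stayed within the random range. Serbp1, an abundant RNA-binding protein gene, is listed at 0 in the knockdown control and at 220 FPKM in the knockdown. Values of 0 in such a gene cannot be read as absence.

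In differentiated cells the knockdown was set against the differentiated control. Of the trophoblast list 8 of 12 genes and of the actin cytoskeleton and SRF list 9 of 16 were at least 2-fold lower. Krt8 was at 65.3 FPKM against 486, Krt18 at 102 against 832, Tagln at 156 against 881, and Acta2, smooth muscle actin, at 1.39 against 17.8. The noncoding RNA H19 was at 2.16 against 50.5 and Tgm1 at 2.02 against 36.4. The ligands Wnt7b and Wnt6 were at 1.77 against 22.3 and at 8.46 against 78.0. Brachyury (T), the primitive streak transcription factor, had a log2 ratio of -1.77 (70.7 FPKM in the control), and Mixl1, a mesendoderm homeobox gene, at 1.95 against 12.2. Among YAP targets Cyr61 was at 61.1 against 231 and Amotl2 at 51.7 against 179, while Ctgf was at 42.1 against 47.4.

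Pluripotency genes were higher under knockdown in differentiated cells. The nuclear receptors Nr0b1 and Esrrb were at 46.2 FPKM against 11.5 and at 86.9 against 30.3, Klf2 at 141 against 48.6, Sox2 at 182 against 76.3 and Otx2, a formative and anterior factor, at 81.0 against 24.0. The metallothioneins Mt1 and Mt2, which bind zinc and other metals, were at 868 against 148 and at 659 against 110. Trh was at 296 against 77.5. Klf4 went the other way, at 5.83 against 9.10.

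Across 11845 genes, 203 were at least 2-fold higher and 565 lower, and 181 and 528 without small RNA rows. Of 25 lists, 6 lay in the upper and 9 in the lower tail. Lower medians were those of trophoblast genes (-1.47, 8 of 12 at least 2-fold lower), actin cytoskeleton and SRF targets (-1.32, 9 of 16), the YAP/TEAD target signature (-1.10, 11 of 19), mesoderm (-0.91, 7 of 14), immediate-early and heat shock genes (-0.88), Hippo pathway components (-0.81, 9 of 21), feeder fibroblast markers (-0.62), endoderm (-0.50) and imprinted genes (-0.33). Feeder fibroblast markers were at percentile 2.80, outside the tail, with a pseudocount of 5, and had 3 genes at 5 FPKM. Upper medians were those of naive pluripotency (0.70, 6 of 20 at least 2-fold higher), formative and primed epiblast (0.47), replication-dependent histones (0.36), the integrated stress and unfolded protein response (0.35), glycolysis and hypoxia (0.31) and general pluripotency (0.25). Cell cycle genes had a median of 0.063, pro-apoptotic genes -0.063 and p53 targets -0.083, all within the random range. Tpm3, a tropomyosin gene, is listed at 0 in the differentiated control and at 87.4 FPKM in the knockdown, and is not read as a difference.

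A joint fit asked what the knockout-labelled libraries and the knockdown share in undifferentiated cells. In the fit without small RNA rows Peg10 had a log2 change of -1.40 (SE 0.14), Dnmt3l of -1.29 (SE 0.13), D630045M09Rik of -3.30 (SE 0.32) and Trh of 1.07 (SE 0.12). With all rows, limma with Benjamini-Hochberg adjustment over 12128 genes called 0 genes higher and 2 lower, Mir5133 and Rnu12. Both are small RNAs listed at 0 in both knockout-labelled libraries and in the knockdown. At an unadjusted p under 0.05 limma gave 336 higher and 483 lower genes. Without small RNA rows Trh rose, and Peg10, D630045M09Rik and Dnmt3l fell, by limma with Benjamini-Hochberg adjustment (adjusted p = 0.0233 for Trh and 0.0130 for each of the others). With the GC trend also removed 3 of these 4 were called, D630045M09Rik narrowly (limma, Benjamini-Hochberg adjusted p = 0.0499), and Dnmt3l was not. Yap1 itself had a log2 change of -1.60 (SE 0.50, limma, Benjamini-Hochberg adjusted p = 0.710). Both calls held when either knockout-labelled library was left out, and the number of further calls varied, with 6 higher and 9 lower calls in all without Yap1_KO1 and 1 and 3 without Yap1_KO2.

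In that fit the YAP/TEAD target signature had a median of -0.19, in the lower tail. Of its 16 members, 0 passed over all genes by limma, against 819 genes in all with an unadjusted p under 0.05. Adjusted over the list alone 5 passed, with Amotl2 (log2 change -1.85), Ctgf (-1.53), Cyr61 (-1.68) and Igfbp3 (-0.69) lower and Nt5e (1.30) higher. Actin cytoskeleton and SRF targets had a median of -0.17, and Cnn2, Flna, Myl9 and Tagln, which bind or move actin filaments, passed when adjusted over the list alone, all lower, where 0 passed over all genes. With the GC trend removed 2 of these, Cnn2 and Myl9, passed. Imprinted genes had a median of -0.38, with Cdkn1c (-0.91) and Peg10 lower and passing when adjusted over the list alone. The lower tail also held trophoblast (-0.46), formative and primed epiblast (-0.22), Nodal and BMP targets (-0.22), neuroectoderm (-0.20), and glycolysis and hypoxia (-0.094). Naive pluripotency (0.10) and germline genes (0.29) lay in the upper tail. At 5 FPKM neuroectoderm (percentile 28.3, with 4 genes) and Nodal and BMP targets (16.5) left the tail, germline genes did so without a filter (87.6), and glycolysis and hypoxia with the GC trend removed (17.9).

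Differentiation itself was read from the control pair. In the differentiated control 11 of 13 mesoderm genes, 15 of 16 actin cytoskeleton and SRF targets and 9 of 12 trophoblast genes were at least 2-fold higher. T was at 70.7 FPKM against 0.0911, Tagln at 881 against 2.31, Krt8 at 486 against 5.98, Cyr61 at 231 against 3.38, and the growth factor binding protein Igfbp3 at 289 against 5.08. Naive genes were lower, with Nanog at 78.4 against 266, Zfp42 (Rex1) at 49.7 against 409 and Klf4 at 9.10 against 82.5. Pou5f1 was at 927 FPKM against 1138. Fgf5, the marker of primed epiblast, was at 16.6 against 0.0191. Of 12436 genes, 1624 were at least 2-fold higher and 1262 lower, and 1590 and 1213 without small RNA rows. With the mean of the 3 undifferentiated controls in place of the knockdown control, 1428 were higher and 917 lower.

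Of the naive list, 17 of 20 genes were at least 2-fold lower (median -1.81), and of the formative and primed list 13 of 15 were at least 2-fold higher (2.23). Upper tails held trophoblast (2.96), mesoderm (2.82), actin cytoskeleton and SRF targets (2.65), YAP/TEAD targets (1.93, 14 of 19), Wnt targets (1.66), interferon response (1.62), feeder fibroblast markers (1.37), Hippo pathway components (1.22), imprinted genes (1.17), endoderm (1.06), p53 targets (0.91), immediate-early and heat shock (0.90), histones (0.73), pro-apoptotic genes (0.68) and Nodal and BMP targets (0.64). Lower tails held germline genes (-1.14), glycolysis and hypoxia (-0.89) and general pluripotency (-0.34). Some left the tails under other settings: endoderm (percentile 96.8), immediate-early and heat shock (96.5) and interferon response (93.2) without a filter, Nodal and BMP targets (94.4) with a pseudocount of 5, and general pluripotency (2.70) with a pseudocount of 0.1. At 5 FPKM the feeder fibroblast (3 genes), interferon (4) and germline (4) lists were too short to be placed. The 2-cell-like list had fewer than 3 measured members in every comparison and gave no value. Glycolysis and hypoxia genes had a median of 0.394 in the knockdown control over ESC, so their lower value in differentiation may depend on the control.

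The response to differentiation was then compared with and without the knockdown. Over 1380 genes with a mean log2 ratio of at least 1, the median log2 ratio was 1.59 in control cells and 1.31 under knockdown. The median difference per gene was -0.26. The response was smaller under knockdown for 65.3% of these genes, by at least 1 log2 unit for 258 genes, and larger by that much for 43. Over 1201 genes with a mean ratio of -1 or below the medians were -1.38 and -1.39, with a median difference of -0.018. This difference of differences has no replicate check.

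**Figure D2:**
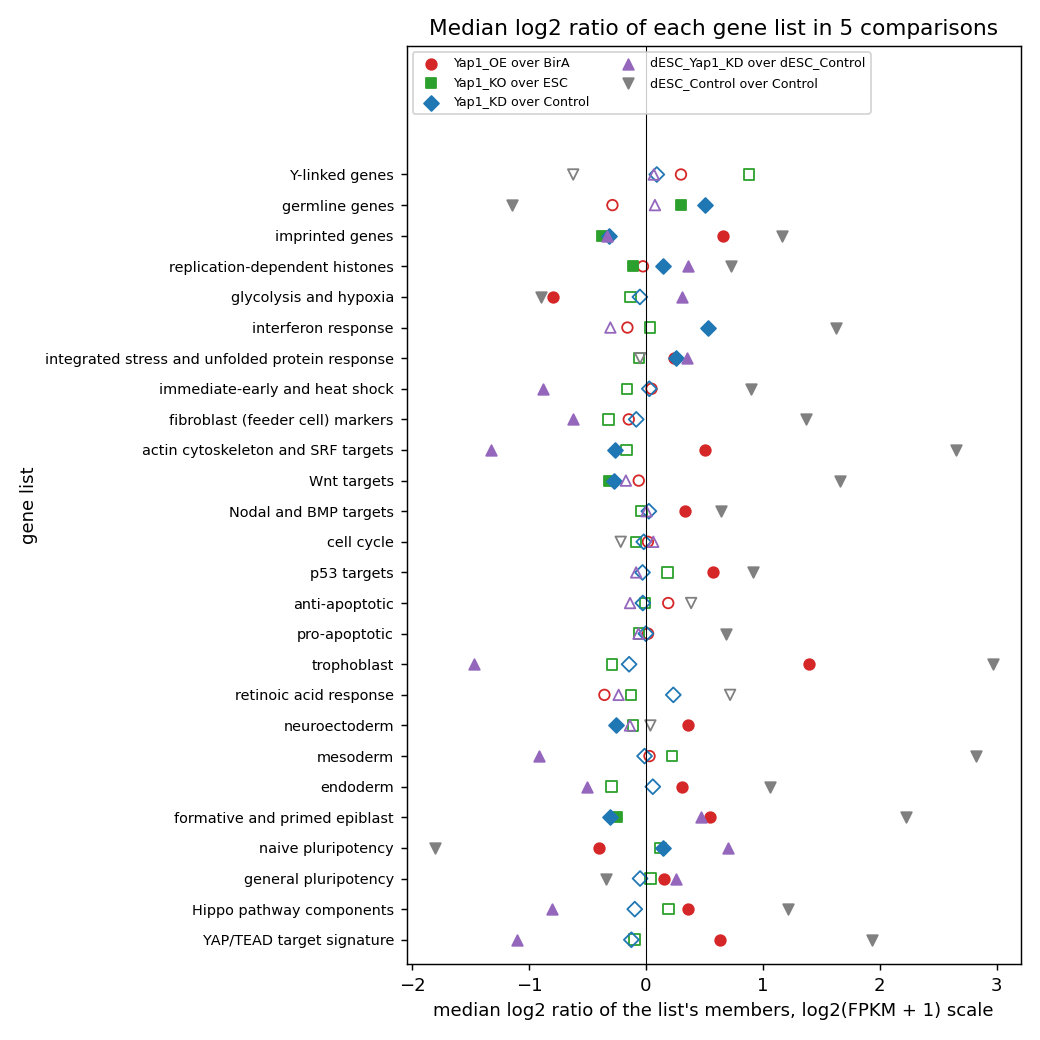
Median log2 ratio of each gene list, on the log2(FPKM + 1) scale, in 5 comparisons; filled symbols mark medians in the outer 2.5% at either end of random lists of matched expression, and open symbols all others or lists under 5 members. Trophoblast genes have a median of 1.40 in the overexpression library, -1.47 under knockdown in differentiated cells and 2.96 in differentiation.

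Log2 ratios of the knockout-labelled libraries and of the knockdown, which share no library, were set against each other across genes at a mean of 5 FPKM or more. Genes are not independent replicates, and 10 such pairs of comparisons were computed. Pearson's r was -0.055 and Spearman's rho -0.17, and rho was -0.064 with the GC trend removed. Over the 8288 genes at a mean of 5 FPKM over all 9 libraries, without small RNA rows, r was -0.0170 (rho -0.151), and with the GC trend also removed 0.0707 (rho -0.0540), so the sign of r is not settled. On the same genes overexpression and the knockout-labelled libraries gave r = -0.0654 (rho 0.0470), and -0.187 (rho -0.0750) with the GC trend removed. Knockdown in ES and in differentiated cells correlated at r = 0.304 without small RNA rows (rho 0.282). Overexpression correlated at -0.241 with knockdown in ES cells (rho -0.335), at -0.252 with knockdown in differentiated cells, and at 0.614 with differentiation of control cells (rho 0.548). The differentiation ratios of control and knockdown cells correlated at 0.872.

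**Figure D3:**
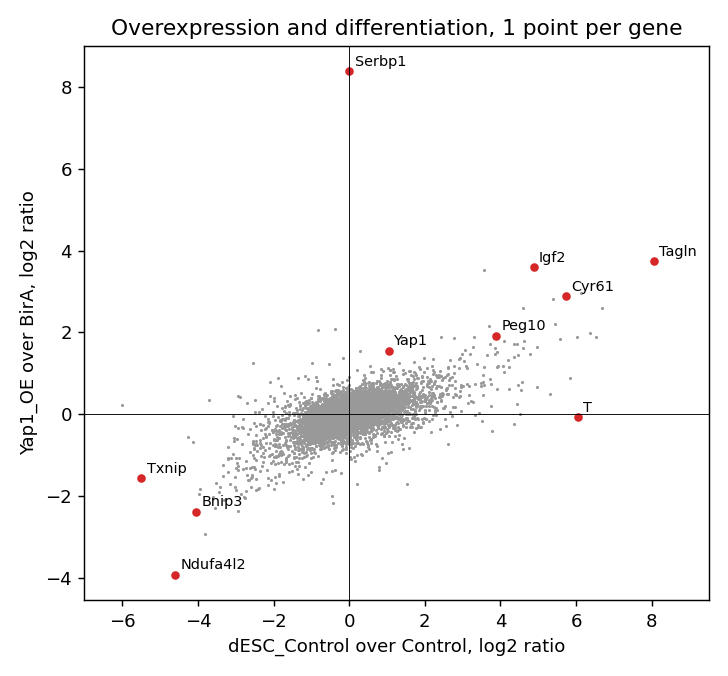
Log2 ratio of overexpression over BirA (vertical) against log2 ratio of the differentiated over the undifferentiated control (horizontal) for 8288 genes at a mean of 5 FPKM or more, small RNAs left out; each point is 1 gene. Tagln, Cyr61, Igf2 and Peg10 are high on both axes and Ndufa4l2 and Bnip3 low on both, T is high only on the horizontal axis, and Serbp1, listed at 0 in BirA, stands apart at the top (r = 0.614).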

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

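The items here are gene groups or genes for which the knockdown ratio pointed in opposite directions in undifferentiated and in differentiated cells, each from 1 library against 1, so the differences were not tested. The tests that weigh the asymmetry of the knockout-labelled libraries were chosen after the result was seen; for GC content the bounds were set before its result, but the correction was added after the data had been examined.

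Formative and primed epiblast genes had a median log2 ratio of -0.31 under knockdown in ES cells, over 11 members with 4 above 0. Under knockdown in differentiated cells the median was 0.47, over 15 members with 10 above 0. Both medians lay in the outer tail of random lists. They cover different sets of members, and how many members changed sign was not counted. Of the members, Pou3f1 (-0.66 and -0.12) and Cldn6 (-0.64 and -0.96) were lower in both comparisons. Dnmt3b, a de novo DNA methyltransferase, was at 19.3 FPKM against 31.1 in ES cells and at 250 against 149 in differentiated cells. Otx2 had a log2 ratio of 0.04 in ES cells and was at 81.0 FPKM against 24.0 in differentiated cells.

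Gm12669 had a log2 ratio of -2.02 under knockdown in ES cells and of 1.03 in differentiated cells. Its values jump between libraries, with 8.09 FPKM in Yap1_KO2 and 0.0058 in Yap1_KO1, so the opposite signs of this gene carry little weight.

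More genes were at least 2-fold lower than higher in both knockout-labelled libraries (91 against 18 without small RNA rows). For the 91 genes an unusual ESC control alone is argued against. Their median log2 ratio over the mean of BirA and the knockdown control was -1.16, with 2 of 91 above 0. The 18 higher genes had a median of 1.12 there, with 18 of 18 above 0. Both sets were chosen on the same knockout-labelled libraries, so part of this is built in. The check does not bear on the excess of lower over higher genes. GC content alone is argued against as well. Once the trend was removed 74 genes were lower and 17 higher, 4.35 lower genes per higher gene. The lower genes had a median log2 ratio of 0.384 in the overexpression library, above all random lists of matched expression. Under knockdown in ES cells their median was -0.149. A loss of Yap1 activity in the libraries labelled Yap1_KO1 and Yap1_KO2 would give these directions, which is a hypothesis only. The higher genes did not show the mirrored direction, with a median of -0.074 in the overexpression library (percentile 24.3, 7 of 16 above 0) and of 0.093 under knockdown in ES cells (percentile 91.9), both within the random range. A library or culture difference shared by that pair stays open, since the labels do not separate it from the knockout.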

How the results depend on the processing

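No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Leaving out a knockout-labelled library left the knockout fit with no residual degrees of freedom, so that fit was not run. Settings without small RNA rows, with the mean of the 3 controls and with the GC trend removed were chosen after seeing the data. For the main results 122 pairings of a result with another setting kept a count within 1.5 times, a call, or a value within its label's range. In 26 pairings a count was larger beyond that bound, in 22 it was smaller, and in 5 a value left its range. For the differentiation response that range is the 95% binomial interval of the median over genes, which are not independent. It is the 3rd range used, after the spread of single genes between the knockout-labelled libraries and their median difference, and it replaced them after the values were seen. The values themselves did not depend on it.

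The 2-fold counts followed the pseudocount, which by construction sets how far low genes can move. With 0.1 FPKM there were 353 higher and 564 lower genes under overexpression, 132 and 109 under knockdown in ES cells, 366 and 859 in differentiated cells, and 68 and 219 in both knockout-labelled libraries. With 5 FPKM the counts were 74 and 94, 39 lower for ES cells, 67 and 257, and 7 and 50, and differentiation gave 772 and 465. Without small RNA rows knockdown in ES cells gave 24 and 28. Setting Yap1_KO2 against the knockdown control gave 14 higher genes, the mean of the 3 undifferentiated controls 41 and 179, and single knockout-labelled libraries 68 to 75 higher and 194 lower.

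The limma calls of the knockout-labelled libraries (2 higher and 18 lower) were 9 and 51 with a robust prior, 10 and 38 without small RNA rows, 0 and 1 with 3 undifferentiated controls, and 0 and 0 without a filter (limma, 3266 genes at an unadjusted p under 0.05). With a pseudocount of 5, and without trend, 1 gene was called higher. The joint fit (0 and 2) gave 1 and 4 with a robust prior, 1 and 3 without small RNA rows, 2 and 18 from the knockout arm alone, 1 to 6 higher and up to 9 lower (from 3) when a knockout-labelled library was left out, 1 lower with a pseudocount of 0.1, a filter at 5 FPKM or no arm term, and 0 lower without a filter (limma, 1354 genes at an unadjusted p under 0.05). Fewer or other genes change the shared spread and the adjustment, and the cause was otherwise not tested.

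The Spearman correlation across genes between the knockout-labelled libraries and the knockdown was -0.071 without a filter and -0.064 with the GC trend removed, so GC content accounts for part of it; the cause of the former was not tested. The difference of -0.018 for genes lower in differentiation had another sign with a pseudocount of 0.1 (0.027), a filter at 5 FPKM (0.020) and removal of the GC trend (0.0021), so its direction is open. For genes higher in differentiation the difference ranged from -0.23 with a pseudocount of 0.1 to -0.33 with 5. List medians that changed sign were Wnt targets (0.0063) in the knockdown in ES cells without a filter, neuroectoderm there at 5 FPKM (0.041), and in the knockout-labelled libraries germline genes without a filter (-0.0013) and, with the GC trend removed, germline genes (-0.073) and histones (0.0085); the cause was not tested. Among the other pairings of a list in a tail with a setting, 388 medians moved by less than the SD of random medians and 124 by more, without a change of sign. Of 74 lists in a tail, 51 stayed there under every setting and 23 did not: 5 left with a pseudocount of 0.1, 5 with 5, 14 without a filter, 15 at 5 FPKM (some with fewer than 5 genes) and 4 with the GC trend removed. Yap1 ratios kept their direction under rescaling. Low genes are limited by depth: at 1 FPKM a 2 kb transcript had about 18.4 fragments in Yap1_KO1.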

Other observations

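The tests on the glycolysis and hypoxia list and on genes shared by 3 arms, and the removal of the GC trend, were chosen after the values were seen, while the bounds for overexpression and differentiation were set before their results.

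A small set of genes differed in opposite directions in the knockout-labelled and knockdown libraries and in the overexpression library, in arms that share no library. At a threshold of 1.5-fold, 25 genes were lower in both knockout-labelled libraries and in the knockdown and higher in the overexpression library, against 0.314 expected from independent arms and 2.28 expected given the 46 genes lower in both the knockout-labelled libraries and the knockdown. Only 2 genes were lower in all of these comparisons and 1 higher in all. The 25 include the YAP targets Ctgf, Cyr61, Amotl2 and Ajuba, the Hippo pathway scaffold Wwc2, the nitric oxide regulator Ddah1, the myosin light chain Myl9, the imprinted Peg10 and Cdkn1c, the Wnt receptor Fzd2 and the tight junction protein Cldn6. With the GC trend removed there were 27. The ratios did not follow Yap1 RNA across the arms: Cyr61, Ctgf, Amotl2 and Ajuba had log2 ratios of -2.04, -1.91, -1.78 and -1.85 in Yap1_KO1, at 87.6% of the control's Yap1 RNA, and of -1.13, -0.82, -1.09 and -0.68 in the knockdown, at 12.2%. Within the pair all 4 were lower in Yap1_KO2 (-2.13, -2.22, -3.07 and -2.17), which had less Yap1 RNA (42.2%). The set was found and counted on the same data. In differentiated cells, which did not enter the choice, 23 of the 25 were below the control under knockdown (median log2 ratio -1.01). The differentiation ratios of 23 of them were above 0 too (median 2.35). Of all genes higher in differentiation 65.3% had a smaller response under knockdown. That share compares responses and not levels against the differentiated control. The share of such genes below that control was not counted, so the result for the 25 is not taken as an independent check.

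The mirror set, higher in both knockout-labelled libraries and the knockdown and lower in the overexpression library, held 14 genes against 0.395 expected from independent arms and 1.59 expected given the 21 genes higher in both the knockout-labelled libraries and the knockdown. Vax2 was at 8.73 and 4.06 FPKM in the knockout-labelled libraries (log2 ratios 1.97 and 1.03), at 7.15 FPKM against 1.84 in the knockdown and at 0.292 against 3.38 in the overexpression library. Vax2os, transcribed next to it from the opposite strand, followed the same order, and without stranded counting the reads of this pair cannot be assigned with certainty. Trh, Grin1, Stmn3 and the germline ribosomal gene Rpl10l were in the set as well. In differentiated cells 1 of the 14 was below the control under knockdown, and the median log2 ratio was 1.15. The differentiation ratios of these genes ran the opposite way (median -1.75, 1 of 14 above 0). Over the 1201 genes lower in differentiation the response hardly differed under knockdown (median difference -0.018, smaller for 47.6%). How many of those genes lay above the control was not counted, so the result for the 14 is not taken as an independent check.

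The metallothioneins Mt1 and Mt2 were at 84.9 and 74.3 FPKM (against 174) and at 47.0 and 52.9 (against 103) in the knockout-labelled libraries. Under knockdown they were at 184 against 150 and 83.8 against 65.0 in ES cells, and at 868 against 148 and 659 against 110 in differentiated cells. The arms were not tested against each other, and each knockdown is 1 library against 1.

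Glycolysis and hypoxia genes were lower in the overexpression library than in BirA (median -0.80). The list differed between control libraries by up to 0.46 (BirA over ESC, 18 of 19 genes higher; 0.394 for the knockdown control over ESC), with Bnip3 at 30.2 FPKM in BirA, 55.1 in the knockdown control and 7.16 in ESC, so a difference of oxygen, density or medium between cultures may account for part of the pattern. Against ESC the overexpression library had a median of -0.38, between the bounds set for and against BirA as the sole source. Whether Yap1 lowers these genes cannot be told apart from the state of the control culture with 1 library of each.

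Overexpression ratios increased with differentiation ratios across genes (r = 0.614). The BirA library as the sole source is argued against by r = 0.433 when the overexpression library was set against ESC. The bootstrap SD of 0.0173 is over genes, which are not independent, and does not cover differences between control libraries. With ESC as control rho was 0.206, where it was 0.548 with BirA, so part of the relation may rest on BirA. GC content is argued against, with r = 0.670 after the trend was removed. A state that sets BirA and the knockdown control apart from ESC stays open, with r = -0.210 for BirA over ESC. A shift of the overexpression library toward a partly differentiated profile is a hypothesis that the single library cannot settle; T, at 0.0465 FPKM there, was not part of it.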
